A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

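RiboMeth-seq reads ribose methylation from alkaline cleavage of RNA, because a 2'-O-methyl group protects the bond on its 3' side and few fragments then begin or end there. Per the labels, whole cell RNA of budding yeast was cleaved by partial alkaline hydrolysis, fragments of 20 to 40 nt were purified, and the libraries were sequenced on the Ion Proton platform. The 8 libraries form 4 groups of 2: a wild type (WT), a strain labelled as a Dbp3 deletion (Delta_Dbp3), and a strain with PRP43 behind a GAL promoter, labelled Gal (PRP43_Gal) or Glu (PRP43_Glu). The media named in the labels hold galactose or glucose, so carbon source and promoter state change together in the PRP43 strain. The series design states biological duplicates. Groups were taken from the sample labels.

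The submitters' processing notes name cutadapt 2.0 and Bowtie2 2.3.4.1, and mapping parameters, reference sequences and filters are not given in the sources used here. Per the file headers, the deposited read-end counts give, for each nucleotide and library, the number of reads with their 5' end there, the number with their 3' end there, and the sum. The authors' score, headed as a percentage but held as a fraction from 0 to 1, was recomputed from the deposited counts. It is 1 minus the read ends at a nucleotide over the mean of the weighted means of 6 neighbours on each side, with weights falling from 1 to 0.5, and values below 0 set to 0. Recomputed and deposited scores differed by at most 5.0e-10 over 41376 values. The authors also deposited group means of the fraction at 55 annotated sites, 18 in 18S and 37 in 25S rRNA, with a header that speaks of a barcode correction. At 6 of the 220 site and group means, covering 5 sites, the deposited mean could be met within 1e-06 only with the score from 5' ends alone in 1 library, and those 6 values were used as the authors gave them. No WT or Delta_Dbp3 value had been replaced in this way. Positions are those of the mature 18S and 25S rRNA as numbered in the deposited tables, and no genome was used here.

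Scores at the 55 sites were tested with limma 3.58.1 in R 4.3.3, in a single fit over the 8 libraries without a block, with empirical Bayes moderation and Benjamini-Hochberg adjustment within each of 5 comparisons at an adjusted p of 0.05. The prior degrees of freedom were 1.31 beside 4 residual ones. With 2 libraries against 2, an exact two-sided permutation test cannot go below 0.333. Calls therefore rest on a normal model, with a variance pooled over the 4 groups at each site and moderated across sites. A scan of all nucleotides of 18S (1800) and 25S (3396) used edgeR 4.0.16, quasi-likelihood, on the sums of read ends with the expected read ends as offset, a mean of at least 50 read ends, an adjusted p of 0.05 and a score difference of at least 0.1. Of the 12 site lists, 11 were tested with camera at a preset inter-site correlation of 0.01 and with an estimated one, and the pair Um2921 and Gm2922 is reported by name. The lists were fixed before the data were examined, by site name for the guide lists and the pair, and by rule for the others. These rules use rRNA and position or, for partly methylated sites, a mean score under 0.9 over all 8 libraries. Guide RNA assignments behind these lists are general knowledge of yeast snoRNAs and come from neither the labels nor the deposited tables. Of the 20 sites listed for guides from polycistronic clusters, 19 are among the 55 sites and Gm2395 is not analysed here. Correlations across sites used 100000 shuffles, two-sided, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

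The named sites follow a rule set before the data were examined. For each main comparison these are at most 25 passing sites by size of change, the 5 U18 and U24 sites, Um2921 and Gm2922, and the 5 largest changes that did not pass. For each other comparison and each scan they are at most 5. Alternatives were another scale (log2 odds, scores kept between 0.01 and 0.99), only the compared groups, a replicate block, other moderation, minimum differences of 0.05 and 0.1, the count test (both ends in every library), 2 neighbours or annotated neighbours left out (both with the barcode correction kept), 5' or 3' ends alone, no barcode correction, at least 100 expected read ends, and each library left out.

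The procedures were tested on simulated data. For the comparison of Delta_Dbp3 with WT, over 55 sites and 50 simulations, limma recovered 49.7% of sites lowered by 0.1 and 90.1% of sites lowered by 0.3. In the latter case 1.9% of the unchanged sites were called. For PRP43_Glu against PRP43_Gal the shares were 55.6% and 89.5%, with 1.4% of the unchanged sites called in the latter case. In these limma simulations the SDs of the sites were shuffled among the sites. The scan, over 5167 nucleotides with read ends multiplied by 0.5 at 200, recovered 72% and 75% in the same order. This change raises the score, so recovery of falls was not simulated for the scan. Both simulations gave all groups equal scatter at a site, and the scan had the same dispersion at all nucleotides. In the data scatter differed between groups, as at Gm2619, with an SD of 0.000963 in WT and 0.37 in Delta_Dbp3. The shares may therefore not hold for these data. Libraries held 5557319 to 14191112 read ends on 18S and 25S. The expected read ends at an annotated site had a median of 957.9 to 2652.5 per library and were at least 197.4.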

Results

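RNA helicases remodel RNA and RNA-protein complexes during ribosome assembly, and the study asked how they bear on snoRNA complexes and on rRNA 2'-O-methylation. Ribose methylation was read at 55 annotated sites in whole cell RNA from yeast lacking Dbp3, a DEAD-box helicase, and from yeast with PRP43, the gene of a DEAH-box helicase, behind a GAL promoter. Each of the 4 groups had 2 libraries. Read ends on 18S and 25S came to 12211596 and 10997180 in WT replicates A and B, 11253781 and 9717799 in Delta_Dbp3, 12390972 and 14191112 in PRP43_Gal, and 5557319 and 7045005 in PRP43_Glu. In WT, 47 of the 55 sites had a mean score above 0.9 and the median score was 0.964. The median was 0.943 in PRP43_Gal, 0.913 in Delta_Dbp3 and 0.819 in PRP43_Glu. Duplicates differed by a median of 0.0133 in WT, 0.0262 in Delta_Dbp3, 0.0187 in PRP43_Gal and 0.0253 in PRP43_Glu.

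Without Dbp3, methylation fell at 15 of the 55 sites and rose at 0. On log2 odds 25 sites fell and 1 rose, Gm2791, named after its values were seen. At all 15, both Delta_Dbp3 libraries lay below both WT libraries, as they did at 38 of all 55 sites. Both PRP43_Gal libraries lay below both WT libraries at 24 of the 55. A stretch of 25S between positions 805 and 908 held 5 of the 15 called sites, and Am807 and Am876 in this stretch did not pass. Am817 fell from 0.934 ± 0.00998 to 0.64 ± 0.0161 (SD, n = 2 here and below; adjusted p = 0.000455), and Gm908 fell from 0.916 ± 0.017 to 0.517 ± 0.0731 (adjusted p = 0.00107). Um898 fell from 0.861 ± 0.0173 to 0.597 ± 0.0788, Gm867 from 0.953 ± 0.0104 to 0.805 ± 0.0575, and Gm805 from 0.968 ± 0.00886 to 0.884 ± 0.0266. In 18S, Um1269 was the single site that passed, at 0.974 ± 0.0128 in WT and 0.577 ± 0.08 in Delta_Dbp3 (adjusted p = 0.00114). From 5' ends alone Um1269 fell by 0.177 and did not pass (adjusted p = 0.0626), and from 3' ends it fell by 0.699. Um898 fell by 0.104 from 5' ends and fell by 0.279 from 3' ends, and passed from neither. Gm867 and Gm805 also passed from neither (adjusted p = 0.0626 each from 5' ends, and 0.303 and 0.663 from 3' ends).

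Of the 5 sites guided by U18 and U24, box C/D snoRNAs encoded in introns, 4 passed, and 5 passed when adjusted over the list alone. Am1449 went from 0.974 ± 0.000108 to 0.73 ± 0.00158, Gm1450 from 0.978 ± 0.0113 to 0.782 ± 0.0689, Cm1437 from 0.972 ± 0.00156 to 0.838 ± 0.0289 and Am649 from 0.985 ± 0.00633 to 0.84 ± 0.00992. Cm650, at 0.966 ± 0.0224 and 0.796 ± 0.0947, did not pass (adjusted p = 0.0791). Gm1450 passed neither from 5' ends alone (adjusted p = 0.11) nor from 3' ends alone (adjusted p = 0.274). As a list, they stood below the other sites in camera with the preset correlation (adjusted p = 0.0415), and not with an estimated correlation (adjusted p = 0.289).

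Farther along 25S, Cm2948 fell from 0.616 ± 0.0485 to 0.263 ± 0.0149, Um2724 from 0.98 ± 0.00567 to 0.785 ± 0.0663, Cm2959 from 0.926 ± 0.0557 to 0.778 ± 0.0448 and Cm2197 from 0.868 ± 0.0732 to 0.726 ± 0.0157. From 3' ends alone, Cm2948 and Cm2197 differed by 0.393 and 0.0342 in the other direction and did not pass. Cm2959 fell by 0.0463 from 5' ends and fell by 0.42 from 3' ends, and passed from neither. Um2724 also passed from neither (adjusted p = 0.105 from 5' ends and 0.49 from 3' ends). The largest mean change was at Um2421, from 0.962 ± 0.0311 to 0.467 ± 0.234 (adjusted p = 0.0338). From 5' ends alone its score differed by 0.0255 in the other direction, and it passed from neither end alone (adjusted p = 0.192 from 5' and 0.421 from 3' ends). Among sites that did not pass, Gm2619 had scores of 0.979 ± 0.000963 in WT and 0.491 ± 0.37 in Delta_Dbp3, and Am876 had 0.936 ± 0.000659 and 0.461 ± 0.349. Cm414 (0.951 ± 0.000987 and 0.839 ± 0.115) and Am807 (0.954 ± 0.0122 and 0.856 ± 0.0579) also did not pass. With edgeR on read ends at the 55 sites these 4 and Cm650 passed. From 5' ends alone Am876 fell by 0.561 and passed (adjusted p = 0.0234), and the other 4 did not. Gm2922, which the protein enzyme Spb1 methylates without a guide RNA, had 0.982 ± 0.0032 and 0.982 ± 0.00636, and its neighbour Um2921 had 0.995 ± 0.00151 and 0.99 ± 0.000618.

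Most called sites were in 25S and in clusters. In 25S 14 of 37 sites fell, against 1 of 18 in 18S (Fisher's exact test, two-sided, p = 0.0118). Among sites with another annotated site within 12 nt, 14 of 32 fell, against 1 of 23 isolated sites (Fisher's exact test, two-sided, p = 0.00157). Of the 32 clustered sites, 28 are in 25S, so these tests overlap and do not separate rRNA from clustering. Both tests count sites as independent units, although the sites share the same libraries and close sites share neighbours in the score. Their p-values therefore do not measure variation between replicates, and the same limit holds for the later Fisher's exact tests. As lists, 25S and 18S sites and clustered and isolated sites did not pass camera (each adjusted p = 0.109, and 0.289 with an estimated correlation). With 20 nt instead of 12, clustered sites had a camera adjusted p of 0.322. In the 5' part of 25S, up to its midpoint, 9 of 14 sites fell (11 adjusted over the list alone), with a camera adjusted p of 0.00236, and an adjusted p of 0.289 with an estimated correlation. Besides this list and that of U18 and U24, no list passed camera (adjusted p from 0.051 to 0.742). All 5 sites of U18 and U24 lie in this 5' part, so both lists overlap and do not separate guide from position. In the 3' part 5 of 23 fell (4 adjusted over the list alone). Of sites of all intron-encoded guides, 4 of 8 fell (5 adjusted over the list alone), of polycistronic guides 5 of 19, and of guides with several targets 8 of 23. Of 28 partly methylated sites, a list drawn from the scores of these libraries and so not independent evidence, 13 fell (16 adjusted over the list alone). Adjusted over the list alone, the counts were 1 in 18S, 14 in 25S, 14 clustered, 0 isolated, 5 for polycistronic guides and 8 for guides with several targets. The number of sites called was 7 with only the compared groups in the fit, 7 without WT replicate A, 8 without WT replicate B, 8 from 5' ends and 4 from 3' ends. Gm908, Am1449 and Am649 kept their call in all 21 alternatives.

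**Figure D1:**
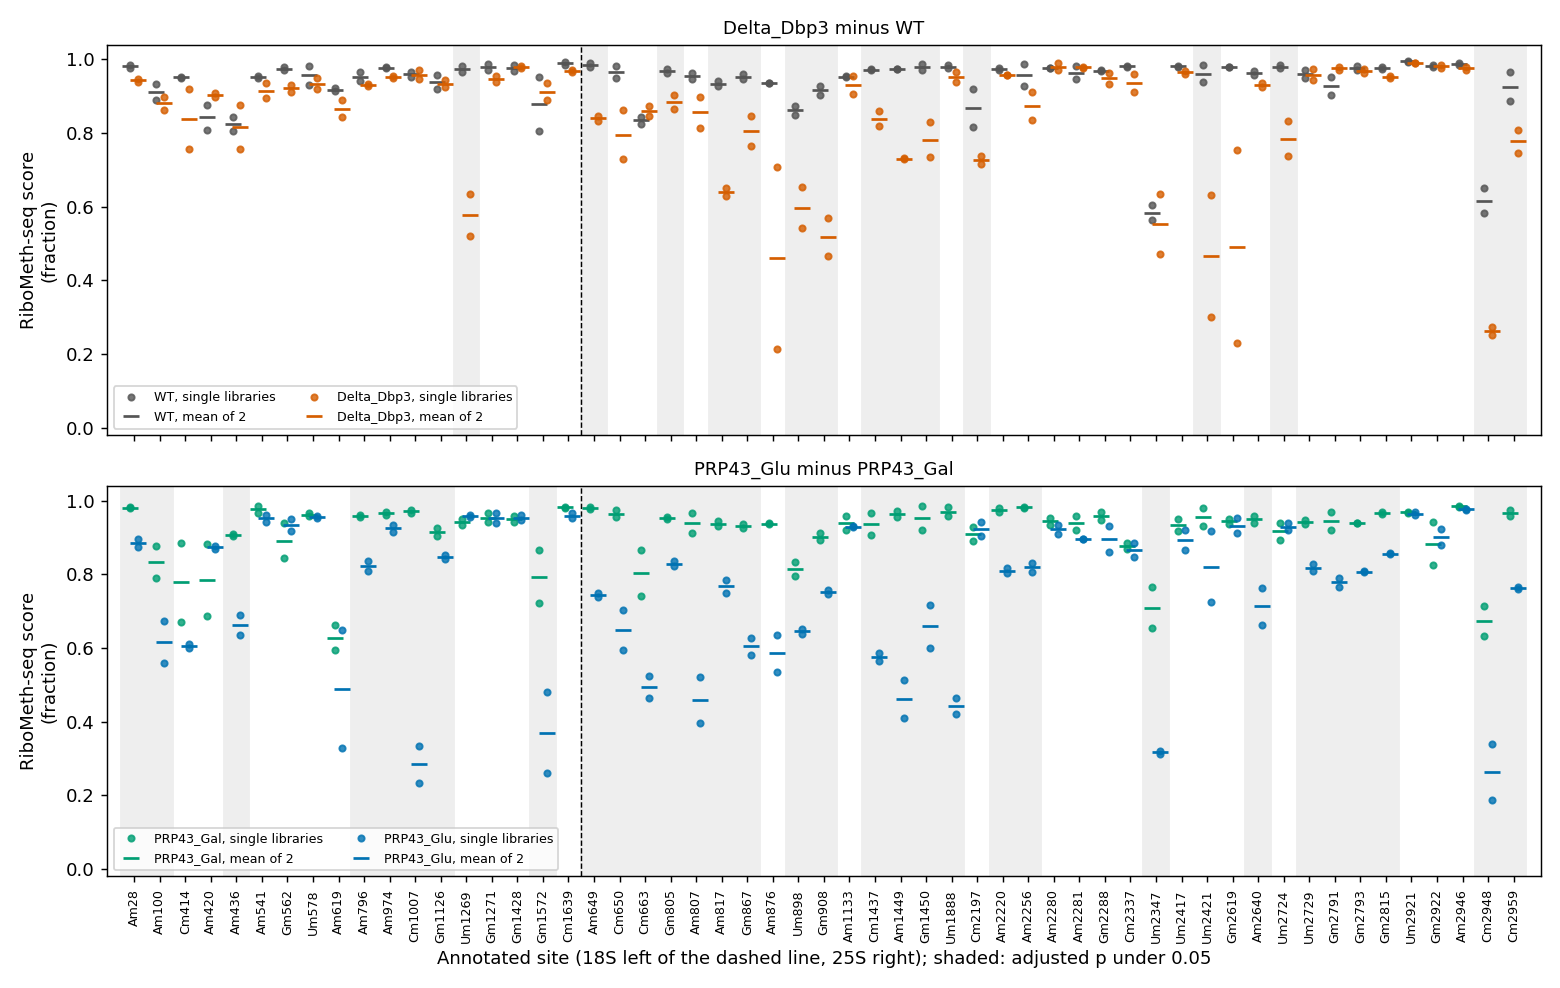
RiboMeth-seq score (fraction, vertical axis) at the 55 annotated sites in order of position (horizontal axis), for Delta_Dbp3 and WT above and for PRP43_Glu and PRP43_Gal underneath; points are single libraries, bars are means of 2, and shading marks an adjusted p under 0.05. Shaded sites number 15 above and 31 underneath, and each has the lower score in Delta_Dbp3 or PRP43_Glu.

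In the PRP43 strain, methylation was lower in glucose, where the GAL promoter is repressed, than in galactose at 31 of the 55 sites, and higher at 0. Without PRP43_Gal replicate B, 27 sites were lower and 3 were higher, Am420, Gm562 and Gm2922. With edgeR, which takes no barcode correction, 32 were lower and 1 was higher, Am541. Gm562 and Am541 are named after their values were seen. At all 31, both PRP43_Glu libraries lay below both PRP43_Gal libraries, as they did at 39 of all 55 sites. Cm1007 in 18S fell most, from 0.971 ± 0.0068 to 0.284 ± 0.0703 (adjusted p = 5.09e-05). In 25S, Um1888 fell from 0.97 ± 0.0168 to 0.442 ± 0.0303 (adjusted p = 3.85e-05) and Am807 from 0.94 ± 0.0394 to 0.459 ± 0.0879 (adjusted p = 0.000739).

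All 5 sites of U18 and U24 fell, also when adjusted over the list alone. Am1449 went from 0.963 ± 0.0126 to 0.461 ± 0.0726, Cm1437 from 0.937 ± 0.0409 to 0.576 ± 0.0145, Cm650 from 0.964 ± 0.0129 to 0.649 ± 0.077, Gm1450 from 0.953 ± 0.0457 to 0.659 ± 0.0824 and Am649 from 0.98 ± 0.00211 to 0.744 ± 0.00662. As a list they did not pass camera (adjusted p = 0.0742). All 8 sites of intron-encoded guides fell, Am807 among them (camera adjusted p = 0.0534).

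In 18S, 8 of 18 sites fell. Gm1572 went from 0.794 ± 0.103 to 0.371 ± 0.157, Am436 from 0.906 ± 0.00354 to 0.663 ± 0.0389, Am100 from 0.833 ± 0.0612 to 0.616 ± 0.0806 and Am796 from 0.958 ± 0.00355 to 0.823 ± 0.0195. In 25S, 23 of 37 fell (Fisher's exact test against 18S, two-sided, p = 0.255). Further decreases of more than 0.3 were found at Cm2948 (0.674 ± 0.0588 to 0.264 ± 0.108), Um2347 (0.71 ± 0.0787 to 0.317 ± 0.00607), Gm867 (0.932 ± 0.00793 to 0.605 ± 0.0328) and Cm663 (0.805 ± 0.0876 to 0.494 ± 0.0426). Smaller ones were found at Am2640 (fell by 0.237), Cm2959 (fell by 0.202), Am817 (fell by 0.17), Um898 (fell by 0.169), Gm2791 and Am2220 (each fell by 0.165), Am2256 (fell by 0.163), Gm908 (fell by 0.151) and Gm2793 (fell by 0.132). The other 6 passing sites changed by less. Um2347 and Cm2959 passed neither from 5' ends alone (adjusted p = 0.112 and 0.205) nor from 3' ends alone (adjusted p = 0.141 and 0.1).

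Sites that did not pass included Am876, with 0.938 ± 0.00223 in PRP43_Gal and 0.586 ± 0.0724 in PRP43_Glu (adjusted p = 0.112; from 5' ends it fell by 0.464, adjusted p = 0.0135), Cm414, with 0.779 ± 0.151 and 0.605 ± 0.0078, Am619, with 0.629 ± 0.0497 and 0.49 ± 0.226, Um2421, with 0.956 ± 0.0353 and 0.821 ± 0.137 (from 5' ends it fell by 0.0527, adjusted p = 0.0135), and Am420, with 0.784 ± 0.138 and 0.874 ± 0.00629. Gm2922 had 0.884 ± 0.0811 and 0.902 ± 0.0299, and Um2921 had 0.969 ± 0.00136 and 0.965 ± 0.00584.

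Clustered sites fell at 17 of 32 and isolated sites at 14 of 23 (Fisher's exact test, two-sided, p = 0.595). In the 5' part of 25S 12 of 14 sites fell, and in the 3' part 11 of 23. The counts were 7 of 19 for polycistronic guides, 14 of 23 for guides with several targets and 20 of 28 for partly methylated sites. Each of these counts was the same when adjusted over the list alone. No list passed camera, whose smallest adjusted p was 0.0534. From 3' ends alone 18 sites passed. Without the barcode correction the change at Um898 was 0.0562 upward and did not pass, and from 5' ends alone in every library Um898 fell by 0.12 and passed (adjusted p = 0.0412).

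**Figure D2:**
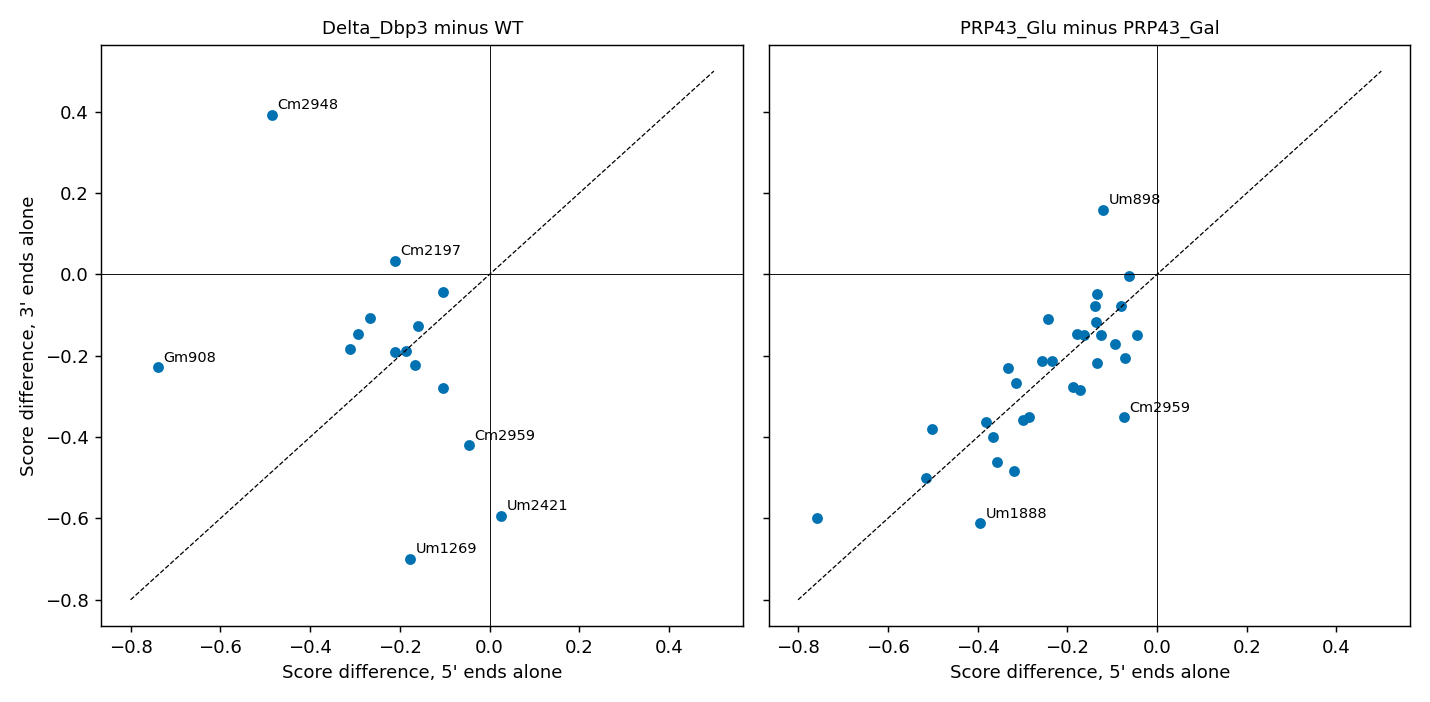
Score difference from 5' read ends alone (horizontal axis) against that from 3' read ends alone (vertical axis) at the 15 sites called in Delta_Dbp3 minus WT (left) and the 31 called in PRP43_Glu minus PRP43_Gal (right); each point is a site, from means of 2 libraries, and the dashed line marks equal values. Um2421 on the left lies at 0.0255 and -0.593, and Um898 on the right is the site with a positive value from 3' ends.

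Both main comparisons called 11 sites, against 8.45 for independent lists (Fisher's exact test, two-sided, p = 0.141). Across the 55 sites, which are not independent replicates, the changes had a Pearson r of 0.134 (permutation p = 0.33) and a Spearman rho of 0.218 (permutation p = 0.11). Without the 2 sites farthest from the median change in Delta_Dbp3, r was 0.225 (permutation p = 0.1). With a library left out, r ranged from 0.0592 without PRP43_Glu replicate A to 0.21 without PRP43_Glu replicate B. The Delta_Dbp3 and PRP43_Glu libraries carried the same 2 barcodes, and WT and PRP43_Gal others, so barcode and group coincide within each main comparison. The test of the difference between both changes passed at 23 sites. At 19 the change was further downward in PRP43_Glu. These were led by Cm1007, where the difference was 0.685 ± 0.0469 (SE), Um1888 (0.499 ± 0.0277), Gm1572 (0.456 ± 0.134) and Am807 (0.382 ± 0.0707). At 4 the change was further downward in Delta_Dbp3, led by Um1269, with -0.413 ± 0.0521. The split of 19 and 4 became 7 and 3 on log2 odds, and 5 and 3 with edgeR. From 5' ends alone the difference at Um1269 was -0.18 and did not pass (adjusted p = 0.115), and from 3' ends it was -0.739. Um1269 had 0.942 ± 0.0119 in PRP43_Gal and 0.958 ± 0.00407 in PRP43_Glu.

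**Figure D3:**
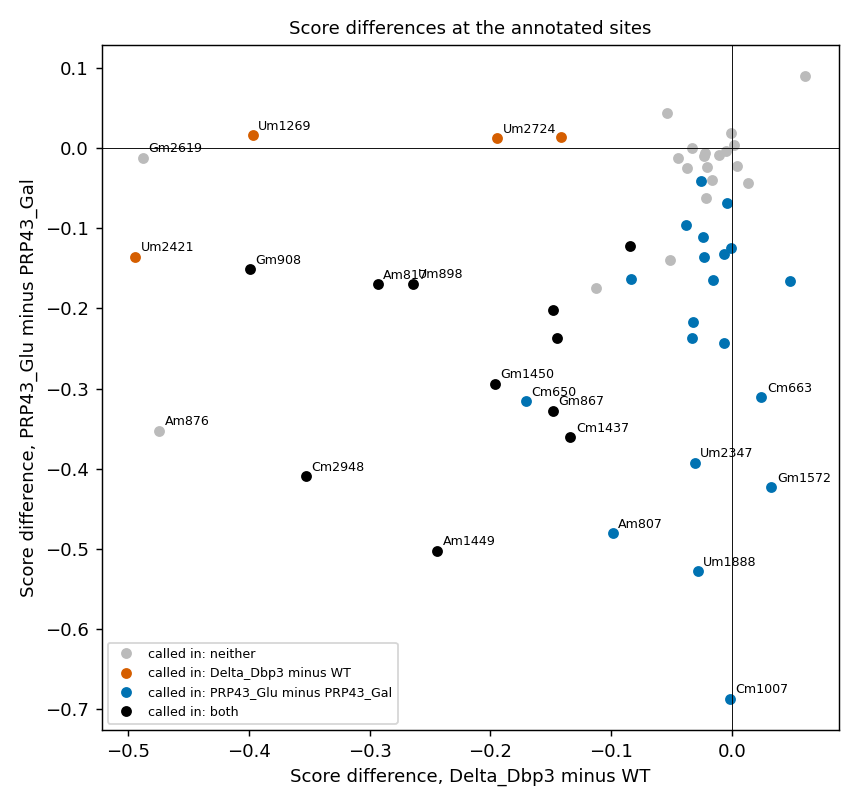
Score difference of Delta_Dbp3 minus WT (horizontal axis) against PRP43_Glu minus PRP43_Gal (vertical axis) at the 55 annotated sites, each difference from means of 2 libraries; colours give the comparison in which a site was called. Cm1007, Um1888 and Gm1572 lie near 0 on the horizontal axis, Um1269 near 0 on the vertical axis, and 11 sites were called in both.

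In galactose the PRP43 strain differed from WT at 0 of 55 sites in the limma fit of scores over all 8 libraries, and 5 had an unadjusted p under 0.05. Limma called 7 on log2 odds, 2 with only the compared groups and 2 with trend and robust moderation, and edgeR on read ends called 10, all lower. In glucose it was lower than WT at 38 sites and higher at 0 (30 and 1 without WT replicate A, the latter Cm2197), led by Cm1007 (fell by 0.676), Um1888 (fell by 0.538), Am1449 (fell by 0.513), Gm1572 (fell by 0.509) and Am807 (fell by 0.495). The WT and PRP43 tables were made with different sets of additional reference RNAs, so strain, medium and processing set cannot be told apart in these comparisons.

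Outside the annotated sites, the scan found 11 of 5117 nucleotides that differed between Delta_Dbp3 and WT, 8 lower and 3 higher, against 10 of 50 annotated sites. The scan left out annotated sites with few read ends. Of its 10 annotated calls, 8 were among the 15 sites called by limma, and the others were Gm2619 (adjusted p = 0.0182) and Am876 (adjusted p = 0.0294). U725 of 18S had a score of 0.681 ± 0.055 in WT and 0 in both Delta_Dbp3 libraries, and U2905 of 25S had 0.648 ± 0.0604 and 0. At both, PRP43_Gal also lay below WT, with 0.0444 ± 0.0628 at U725 and 0.156 ± 0.221 at U2905, and PRP43_Glu had 0.000922 ± 0.0013 and 0. The neighbours G2474 and G2475 of 25S had 0.56 ± 0.0685 and 0.85 ± 0.0197 in WT, with 0 and 0.241 ± 0.341 in Delta_Dbp3, 0.446 ± 0.0699 and 0.657 ± 0.0129 in PRP43_Gal, and 0.0115 ± 0.0162 and 0.403 ± 0.212 in PRP43_Glu. A2911 of 25S was higher in Delta_Dbp3, at 0.529 ± 0.00997 against 0 in WT and in both PRP43 groups. The count outside annotated sites rested on single libraries: it was 0 without WT replicate B, 2 without WT replicate A, 4 and 5 without PRP43_Gal replicate A or B, 1 without either PRP43_Glu replicate, 130 without Delta_Dbp3 replicate A and 58 without replicate B. The 10 annotated sites became 0 without WT replicate B, 1 without WT replicate A, 2 and 3 without PRP43_Glu replicate A or B, and 9 to 11 without each other library. They became 7 with a replicate block and 2 of 7 with a minimum of 500 read ends. For PRP43_Glu against PRP43_Gal the edgeR scan called 0 of 5117 nucleotides outside the annotated sites and 6 of 50 annotated ones. The latter became 15 of 50 with limma on log2 ratios, 13 of 50 with 2 neighbours, 13 of 55 without a minimum of read ends, 0 of 7 with a minimum of 500, and 4 of 50 with a replicate block. They became 1 and 3 without PRP43_Gal replicate A or B (1 of these 3, Am541, was higher), 2 without either PRP43_Glu replicate, 9 without either WT replicate and 7 without either Delta_Dbp3 replicate.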

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

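The tests weighed here, on 5' and 3' read ends, on the share of sites that were lower and on nucleotides outside the annotated sites, were chosen after related values had been seen, and a test with thinned libraries, chosen before, was dropped because random thinning leaves the expected score unchanged.

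The test of the difference between both main comparisons flagged 23 sites, of which 9 were also called on log2 odds and 7 with edgeR. Positive values mean that the score changed further downward in PRP43_Glu than in Delta_Dbp3. In 18S these were Cm1007 (0.685), Gm1572 (0.456), Am436 (0.238), Am796 (0.112) and Am28 (0.0583). In 25S they were Um1888 (0.499), Am807 (0.382), Um2347 (0.362), Cm663 (0.336), Am1449 (0.258), Cm1437 (0.227), Gm2791 (0.213), Am2640 (0.204), Gm867 (0.179), Am2220 (0.149), Gm2793 (0.125), Um2729 (0.124), Am649 (0.0917) and Gm2815 (0.0869). At Gm1572, Cm663 and Gm2791 the score was higher in Delta_Dbp3 than in WT, by 0.0328, 0.0246 and 0.0481, without passing. The score changed further downward in Delta_Dbp3 at Um1269 (-0.413), Gm908 (-0.248), Um2724 (-0.207) and Am817 (-0.124). Among these 4, Gm908 and Am817 also fell in PRP43_Glu, and from 5' ends alone Um1269 did not pass.

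Read ends on additional reference RNAs, which enter no comparison of sites, were flagged where both libraries of the helicase group exceeded both control libraries. Per 1000000 read ends on 18S and 25S, the U2 reference was 2.56 times higher in PRP43_Glu than in PRP43_Gal and the U1 reference 1.28 times higher. The U4, U5 and U6 references were not flagged, with ratios of PRP43_Glu to PRP43_Gal means of 0.57, 0.732 and 0.899. The snR63 reference with flanks was 1.4 times higher in Delta_Dbp3 than in WT. With 2 libraries each, no permutation p under 0.333 is possible.

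The first pattern is the fall of Um2421 in Delta_Dbp3. The score from both ends fell by 0.494, from 3' ends it fell by 0.593, and from 5' ends alone it changed by 0.0255. A bias at 3' read ends may account for it. Scores from 3' ends were 0.238 and 0.5 in Delta_Dbp3 replicates A and B, against 0.938 and 0.987 in WT. The PRP43_Glu libraries with the same barcodes, B and A in that order, had 0.0779 and 0.537. PRP43_Gal replicates A and B, with other barcodes, had 0 and 0.914. At Um1269, PRP43_Glu replicates A and B had 3' scores of 0.923 and 0.91. The authors' values at Um2421 are from 5' ends in 1 PRP43_Gal and 1 PRP43_Glu library, but not in Delta_Dbp3. A biological change read only by 3' ends was not tested.

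The next pattern is the general fall at called sites. In Delta_Dbp3, the 15 sites changed by a median of -0.196 from the main score and -0.186 from 5' ends alone, where 14 were lower. At these sites the fall was thus not confined to 3' ends. The score that called them includes the 5' ends, so this median is not independent of the choice and does not decide on a bias. From 5' ends alone 8 sites passed, 7 of them among the 15. A bias at 3' ends stays open, most plainly at 4 sites, Um2421, Um1269, Um898 and Cm2959, with a 5' change under 50% of the main change. In PRP43_Glu, the 31 sites changed by a median of -0.217 and, from 5' ends alone, by -0.188, with all 31 lower there. These sites were also called from a score that includes the 5' ends, so the same limit holds. A bias at 3' ends stays open here too, most plainly at 3 sites with a 5' change under 50%, Am28, Am2220 and Cm2959. Fewer read ends widen the scatter of a score and would move sites both ways. In PRP43_Glu 48 of all 55 sites were lower (a share of 0.873, 95% binomial interval 0.755 to 0.947). The interval takes the sites as independent, although they share libraries. Against WT, 48 sites were lower in Delta_Dbp3. In PRP43_Gal 40 were lower, although 0 were called in the main fit and its libraries held more read ends than those of WT. A lean to lower scores thus also arose without lower depth, so the share alone does not identify a cause. Random loss of read ends leaves the expected score unchanged. Annotated sites had at least 262 and 336 expected read ends in PRP43_Glu replicates A and B. The median change of -0.135 over all 55 sites therefore argues against fewer read ends as its cause. Other library differences that came with the depth, a bias shared by both ends, carbon source and growth stay open beside a loss of the helicase.

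The last pattern is the weak relation between both main comparisons. Delta_Dbp3 and PRP43_Glu were sequenced with the same library barcodes, which WT and PRP43_Gal did not carry. On log2 ratios of read ends, the changes correlated at 0.175 over the 55 annotated sites and at 0.231 over 5117 nucleotides that are not annotated. The correlation across sites is thus no larger than at nucleotides without annotated methylation, though both were not tested against each other. In scores the relation was not established (Pearson r of 0.134, permutation p = 0.33). Shared barcodes, or anything else that both comparisons share, may account for such a correlation.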

How the results depend on the processing

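The 5'-end score at corrected sites in every library, the correlations from 5' or 3' ends, and crossed letters were chosen after seeing the data. Of the named passing sites, 3 of 15 in Delta_Dbp3 minus WT and 14 of 25 in PRP43_Glu minus PRP43_Gal kept their call in all 21 alternatives chosen before the data were examined. For Delta_Dbp3 minus WT the 15 calls became 26 on log2 odds (25 lower, 1 higher), 7 with only the compared groups, 8 from 5' ends, 4 from 3' ends, and 7 to 16 with a library left out. The 31 calls of PRP43_Glu minus PRP43_Gal, all lower, became 18 from 3' ends, and 32 lower and 1 higher with edgeR. From 3' ends, the 38 calls of PRP43_Glu minus WT became 23. The 0 calls of PRP43_Gal minus WT became 7 on log2 odds, 2 with only the compared groups, 2 with trend and robust moderation, 10 with edgeR, and 0 to 1 with a library left out. The 23 differences became 10 on log2 odds, 8 with edgeR, 11 from 3' ends, and 15 to 24 with a library left out. The direction turned for Um2421 in Delta_Dbp3 (0.0255 from 5' ends, at the corrected sites or throughout) and, from 3' ends, for Cm2948 (0.393) and Cm2197 (0.0342). In PRP43_Glu it turned for Um898: 0.212 on the log2 scale with edgeR, which takes no barcode correction, 0.0562 without that correction, and 0.16 from 3' ends. The correlation across sites was -0.0546 from 3' ends. The 2 lists called in Delta_Dbp3 became 0 with an estimated correlation. The 11 nucleotides of the Delta_Dbp3 scan became 7 with a minimum of 500 read ends, 1 with the replicate block, and 0 to 130 with a library left out. The cause was not tested. With the replicate block the sites called numbered 12 in Delta_Dbp3 minus WT and 30 in PRP43_Glu minus PRP43_Gal. Differences between A and B correlated at -0.0527 and -0.276 across the groups of these comparisons, and with crossed letters the latter had 31 calls. Leaving out a library leaves a group with 1, which is assumed to vary like the others. The minimum of 100 expected read ends removed no site.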

Other observations

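The largest difference between duplicates within each group was 0.524 at Gm2619 in Delta_Dbp3, 0.32 at Am619 in PRP43_Glu, 0.214 at Cm414 in PRP43_Gal and 0.147 at Gm1572 in WT. At 20 of the 55 sites neither main comparison made a call, among them Am2280, Am2281, Gm1271, Gm1428 and Am2946, which were chosen after their values were seen.

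Read ends on the RDN58-1 reference, per 1000000 on 18S and 25S, were 158662 and 102222 in PRP43_Gal and 71106 and 78711 in PRP43_Glu. For the U18 reference with flanks they were 169.1 and 108.6 in WT and 161.4 and 268.99 in Delta_Dbp3. For the U24 reference with flanks they were 69.3 and 50.6 in WT and 66.6 and 42.6 in Delta_Dbp3.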
